A study of Mus musculus with 4 samples.

How the data were processed

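Single-cell RNA sequencing of CD45+ cells from mouse tumours was analysed. Per the labels' protocols, MC38 colon carcinoma cells were grown in the flank of mice that report expression of the interleukin-12 p40 chain by a yellow fluorescent protein. After 7 days, mice were left untreated or received 5 mg/kg of an agonist antibody against CD40, a receptor of antigen-presenting cells. Tumours were taken 2 days later, and live CD45+ cells (blood-derived cells) were sorted and encapsulated by inDrops, a droplet method that tags each RNA molecule with a unique molecular identifier (UMI). The cells came from 3 tumours, 1 untreated and 2 treated, which were spread over 12 libraries and 4 sequencing pools. Pools 1 and 2 each held libraries of the untreated tumour and of anti-CD40 tumour 1, and pools 3 and 4 held libraries of anti-CD40 tumour 2 alone.

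The deposited values were whole-number counts of UMIs per cell and gene, which the authors had not normalised. Per the submitters' processing notes, bcl2fastq, STAR and the genome build GRCm38 were used; their versions, the counter, the annotation, the use of strand, the cell filters and the treatment of doublets are not given in the sources used here. A table of names per cell deposited by the authors gave the pool, library, animal and condition, 1 of 7 major cell types, and 1 of 6 subsets for neutrophils (N1a, N1b, N2, N3, N4 and N5). The number 1 or 2 of the treated tumours was the authors' animal number. The authors' annotation pooled monocytes, macrophages and dendritic cells in a class, which was kept and is called myeloid cells other than neutrophils below. No cell was removed, and no doublet caller was run; instead, cells with at least 3 UMIs of the markers of a second cell type were counted and left out as an alternative.

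Depth differed between the conditions. The median was 433 UMIs per cell in the untreated tumour, 979 in anti-CD40 tumour 1 and 865 in anti-CD40 tumour 2. The lowest count of a cell was 180 UMIs, and the smallest cell of a library lay between 180 and 404 UMIs, so that minima were not the same for all libraries. Shares of cells carry exact Clopper-Pearson 95% intervals, and levels carry exact Poisson or conditional binomial 95% intervals, all of which cover counting error only. A count of 0 was read as an upper limit of 3 counts summed over the tumour, and folds against it are lower bounds.

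For gene tests, UMIs were summed per tumour and cell type, since cells and libraries of a tumour are technical parts of it. The sums were compared with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, robust quasi-likelihood F test), with Benjamini-Hochberg adjustment over the genes tested in a cell type and a threshold of 0.05. Errors of log2 fold changes are standard errors derived from the F statistic. With 1 untreated and 2 treated tumours the fit has 1 residual degree of freedom, and the lone untreated tumour is assumed to vary like the treated ones. The prior degrees of freedom were estimated as infinite in neutrophils, mature dendritic cell-like cells, T cells and NK cells and as 15.5 in the other myeloid cells, so that the p-values rest mostly on a variance shared over genes and, where infinite, taken as known. Differences in treatment effect between neutrophils and the other myeloid cells were tested as an interaction in a joint fit with the tumour as a block. Shares of cell types were not tested across tumours, because 1 against 2 tumours cannot give a small exact p; a difference was called larger than the spread only where it exceeded the whole range over the libraries of each condition.

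Before the data were examined, 22 gene lists were fixed. They covered type I interferon, interferon gamma, major histocompatibility complex (MHC) class I and class II, mature circulating neutrophils, SiglecF-high tumour neutrophils, NF-kB, glycolysis and hypoxia, suppressive myeloid cells, dendritic cell maturation, chemokines for T and NK cells, chemokines for myeloid cells, cytotoxic effectors, exhaustion, regulatory T cells, proliferation and dissociation stress. Signs of RNA quality and of other cells were covered by ribosomal protein, mitochondrial, tumour epithelial, fibroblast and endothelial, and red cell and platelet genes. Lists with at least 3 measured genes were tested with camera in limma 3.58.1, with the preset correlation of 0.01 and with an estimated correlation. Lists were planned for cell types with at least 50 cells per condition. Neutrophils (49 untreated cells) and NK cells (41 untreated cells) lay below this minimum, so that their lists were added after seeing the data and adjusted as a separate family. B cells (20, 2 and 5 cells) were not tested, and lists were not tested in the mature dendritic cell-like cells (44 untreated cells).

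The myeloid cells other than neutrophils were clustered to find dendritic cells, with scanpy 1.11.5 and igraph 0.11.9 (counts scaled to 1000 per cell, 1500 variable genes, 20 components, 15 neighbours, resolution 1.0). A cluster was named only with at least 3 fixed markers of the type among its top 10 genes. Of 15 clusters, cluster 1 was named mature dendritic cell-like, cluster 5 macrophage-like, cluster 7 monocyte-like, cluster 10 T cell-like and cluster 15 neutrophil-like; the other clusters stayed unnamed.

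The genes named in the text were set by a rule fixed beforehand. It took up to 10 genes with the largest change in each direction among genes past the threshold, plus up to 4 members of each list that passed, or 2 members where none did, plus genes set beforehand, among them Cd40 and Irf1. Genes with 0 UMIs in a group are given as "at least", and genes with 1 to 3 UMIs as a ratio of the summed counts with its counting interval. Coordinates are those of GRCm38 in the GENCODE vM21 annotation, matched by symbol; the annotation the authors used may differ. Genes with near-identical copies, and some genes with exons that overlap another gene, are named as uncertain. Other named genes with such overlaps are not marked where they appear, among them Tgm2, Bhlhe40, Jund, Rbbp4, Cd81 and Cd74. Their counts are uncertain in the same way.

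The tests were checked on 10 sets of simulated counts per cell type, each with 200 changed genes. Counts were drawn with the variance trend of the same fit, equal in all tumours. The assumptions on variance were thus built in and not tested, and recovery in real data may be lower. Of genes changed 8-fold, the test recovered 21.2% in neutrophils, 84.7% in the other myeloid cells, 69.4% in mature dendritic cell-like cells, 75.0% in T cells and 80.9% in NK cells. Of genes changed 2-fold, it recovered 0.149%, 5.37%, 9.40%, 13.3% and 8.66% in the same order. In the interaction, 3.79% of 8-fold changes were recovered. Alternatives chosen beforehand were DESeq2 1.42.0 size factors and plain library size in place of TMM, no filter on low counts, the DESeq2 Wald test, each pool left out, single pools, each treated tumour left out, cells thinned to 300 UMIs, cells of at least 500 UMIs, and the tenth of cells with the fewest UMIs left out. Alternatives added after seeing the data left out cells with markers of a second type, neutrophil subsets N1a and N1b, or named clusters. Other software was Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.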

Results

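The data held 4440 CD45+ cells with 3961141 UMIs over 22631 genes. The untreated tumour gave 1399 cells and 707889 UMIs in 4 libraries, anti-CD40 tumour 1 gave 1226 cells and 1391113 UMIs, and anti-CD40 tumour 2 gave 1815 cells and 1862139 UMIs, the treated tumours together in 8 libraries. Pools 1 to 4 held 1010953, 1088049, 697724 and 1164415 UMIs. The comparisons asked which blood-derived cells of the MC38 tumour, and which of their genes, differed 2 days after an agonist of CD40, with 1 untreated and 2 treated animals. With 1 residual degree of freedom, the p-values rest mostly on a variance shared over genes.

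Neutrophils, short-lived phagocytes that enter tissue from the blood, made up a larger share of CD45+ cells in both treated tumours than in the untreated tumour. Their share was 3.50% (95% Clopper-Pearson interval 2.60 to 4.60, 49 cells) in the untreated tumour, 57.1% (54.3 to 59.9, 700 cells) in anti-CD40 tumour 1 and 11.8% (10.4 to 13.4, 215 cells) in anti-CD40 tumour 2. The 2 treated tumours thus differed from each other 4.82-fold, and from the untreated tumour 16.3-fold and 3.38-fold. Monocytes, macrophages and dendritic cells, annotated as a single class, made up 81.2% (79.1 to 83.2), 36.5% (33.8 to 39.3) and 73.3% (71.2 to 75.3). T cells made up 10.7% (9.15 to 12.5), 3.92% (2.90 to 5.16) and 7.44% (6.27 to 8.74), and NK cells, which kill infected or stressed cells, 2.93% (2.11 to 3.95), 2.28% (1.52 to 3.28) and 7.05% (5.92 to 8.33). B cells numbered 20, 2 and 5, plasmacytoid dendritic cells 1, 0 and 2, and basophils 2, 0 and 0. These are shares of sorted cells, so that a rise of a type lowers the others.

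All 8 treated libraries lay above all 4 untreated libraries in neutrophil share (10.6% to 60.3% against 2.68% to 4.52%), and all 8 lay below them in T cell share (2.51% to 8.22% against 8.77% to 13.4%) and in the share of the other myeloid cells (33.1% to 73.9% against 79.1% to 85.5%). The neutrophil share of the pooled treated cells exceeded the untreated share by 26.6 percentage points, which was less than the range of 49.7 points over the treated libraries. By the rule set beforehand no difference in cell type share was larger than the spread. Within pool 1 the neutrophil share was 3.39% untreated and 56.4% treated, and within pool 2 it was 3.65% and 57.6%. The T cell share was 9.24% and 3.35% in pool 1 and 12.5% and 4.31% in pool 2, and the NK cell share was 3.26% and 2.37% in pool 1 and 2.54% and 2.23% in pool 2. Pools 3 and 4 held treated cells only. Falls in the share of other types follow in part from the larger number of neutrophils, and shares among cells other than neutrophils were not computed. Set against the other myeloid cells (1136, 448 and 1330), NK cells (41, 28 and 128) were more frequent in both treated tumours. T cells (150, 48 and 135) were less frequent by that measure.

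**Figure D1:**
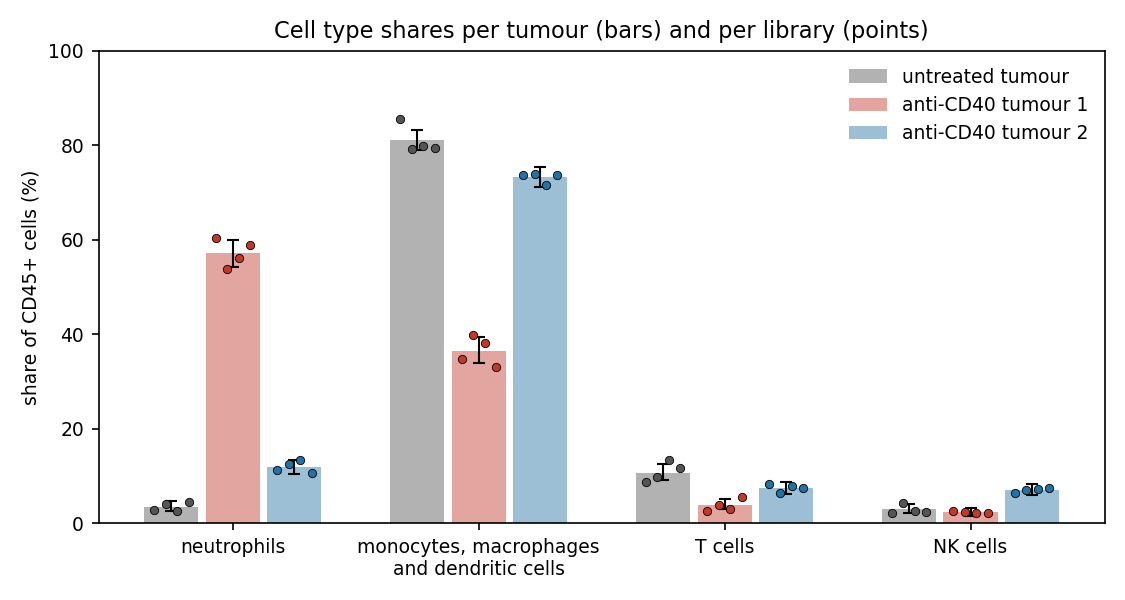
Share of CD45+ cells (percent) of 4 cell types in the untreated tumour (grey), anti-CD40 tumour 1 (red) and anti-CD40 tumour 2 (blue); bars are shares of all cells of a tumour, error bars exact 95% binomial intervals (counting error only) and points single libraries. The neutrophil bars stand at 3.50%, 57.1% and 11.8%, and the libraries of a tumour lie close together.

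Among neutrophils, the annotated subsets N1a and N1b together made up 8.16% (2.27 to 19.6, 4 of 49 cells) in the untreated tumour, 39.4% (35.8 to 43.2) in anti-CD40 tumour 1 and 14.0% (9.62 to 19.3) in anti-CD40 tumour 2. N1a was found in 0 of 49 untreated cells, which allows a share of up to 7.25%, and in 18.3% and 7.44% of the treated cells. N2 made up 28.6%, 28.0% and 20.5%, N3 30.6%, 18.7% and 34.4%, N5 28.6%, 13.7% and 30.7%, and N4 4.08%, 0.143% and 0.465%. Within pool 1, N1a and N1b together made up 3.85% of untreated and 37.4% of treated neutrophils, and within pool 2 13.04% and 40.8%. The untreated interval overlapped that of anti-CD40 tumour 2.

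In neutrophils, Mmp8, Lcn2, Retnlg and Ngp were among the genes that rose after anti-CD40. Mmp8 (chromosome 9, 7558456 to 7568485), which encodes a collagenase of the specific granules, rose by a log2 fold change of 4.51 ± 0.96 (SE; adjusted p = 0.00173), from 163 CPM (UMIs scaled to depth) to 4514 and 2926 CPM in anti-CD40 tumours 1 and 2. Lcn2 (chromosome 2, 32384633 to 32388252), for the iron-scavenging lipocalin, rose by 4.14 ± 0.91 (adjusted p = 0.00335), and Retnlg, for a resistin-like protein of neutrophils, by 3.31 ± 0.86 (adjusted p = 0.0405). Ngp (chromosome 9, 110419747 to 110423012), a granule gene of maturing neutrophils, had 0 UMIs in the untreated tumour and 3057 and 936 CPM in the treated tumours, at least 20.4-fold higher (adjusted p = 8.67e-05). Ifit2 (chromosome 19, 34550694 to 34576419), an antiviral gene induced by interferon, went from 0 UMIs to 346 and 468 CPM, at least 4.16-fold higher (adjusted p = 0.0427).

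Genes with 1 to 3 untreated UMIs also rose. The ratio of summed counts was 72.2 (counting interval 12.95 to 2855) for Wfdc21, 36.3 (12.4 to 176) for Ifitm6, 15.7 (5.37 to 76.3) for Lrg1, 25.0 (4.47 to 989) for Ly6c2 and 14.7 (4.04 to 121) for Chil3; counts of Ifitm6, Ly6c2 and Chil3 are uncertain because near-identical genes exist. Mcemp1 rose by 3.43 ± 0.92 (adjusted p = 0.0451). Sdf4, for a calcium-binding protein of the Golgi, fell by 2.96 ± 0.74 (adjusted p = 0.0287). Values were 0.91 ± 0.81 for Cxcl2 (adjusted p = 0.693), 0.39 ± 0.76 for Il1b (adjusted p = 0.875) and -1.10 ± 0.65 for Irf1 (adjusted p = 0.512), none of which passed. In neutrophils thinned to 300 UMIs, Mmp8 was detected in 2.44%, 45.4% and 19.5% of cells and Lcn2 in 2.44%, 64.5% and 35.5% (untreated tumour, anti-CD40 tumours 1 and 2), with 8, 33 and 15 shallower cells left out. Without thinning the shares were 6.12%, 59.4% and 27.9% for Mmp8 and 8.16%, 74.9% and 45.1% for Lcn2. In thinned T cells, which should lack both, neither exceeded 2.13%, with median depths before thinning of 435, 926 and 668 UMIs in neutrophils and 475.5, 778 and 651 UMIs in T cells.

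In neutrophils 12 of 2713 genes passed the threshold, 11 higher and 1 lower, and 295 had an unadjusted p below 0.05. The median log2 change over all genes was 0.29 with TMM and -0.28 with plain library size, under which 5 genes were higher and 7 lower, 6 of them shared. All 12 genes kept their direction within pool 1, within pool 2 and in each treated tumour. Here and in the other cell types, these are parts of the sums from which the genes were called. A kept direction is therefore not an independent check. Only 49 untreated neutrophils with 23468 UMIs stood behind the comparison, and 3, 23, 7 and 20 genes passed with pool 1, 2, 3 or 4 left out. Of the 12 genes, 2 still passed without subsets N1a and N1b, and 5 in cells thinned to 300 UMIs, with the direction kept by all 12 in both.

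**Figure D2:**
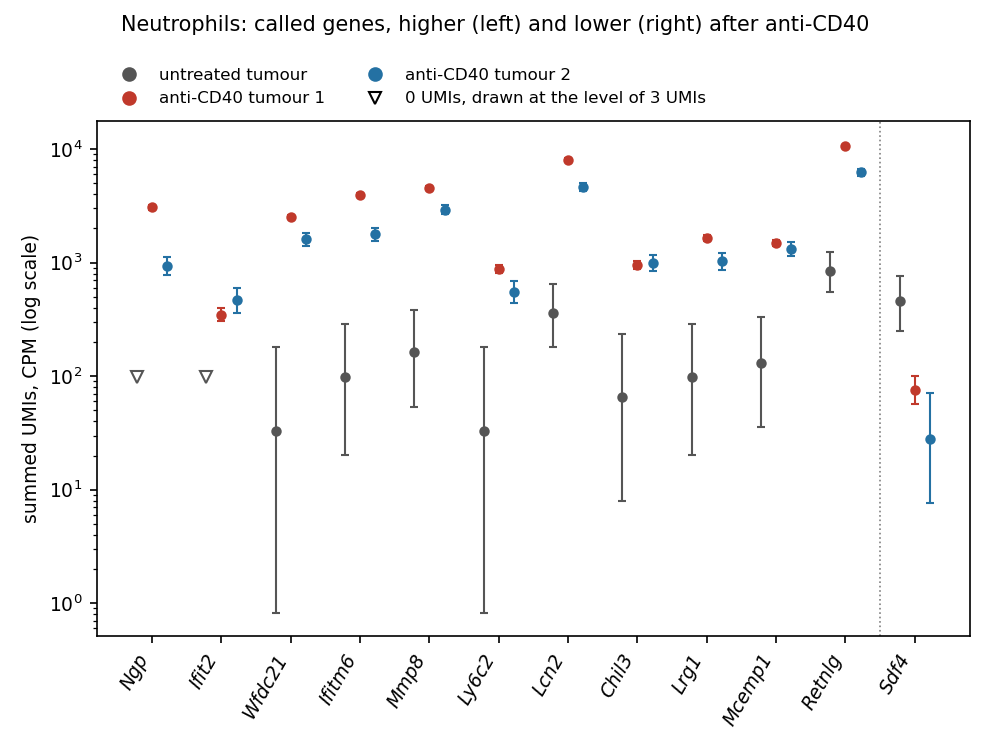
Level in neutrophils (summed UMIs as CPM, log scale) of the 12 genes that passed, in the untreated tumour (grey), anti-CD40 tumour 1 (red) and anti-CD40 tumour 2 (blue). Error bars are 95% Poisson counting intervals, and open triangles mark 0 UMIs, drawn at the level of 3 UMIs. Lcn2 stands at 359, 8062 and 4617 CPM, and Sdf4, right of the dotted line, at 457, 76.0 and 27.9 CPM.

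The list of mature circulating neutrophil genes (24 measured) rose as a group in neutrophils. Its median log2 change was 2.60, or 2.01 with genes at 0 UMIs set to their bound. Adjusted p was 2.28e-21 with the preset correlation, and p = 0.266 with an estimated correlation. Of its members 7 rose and 0 fell, 16 passed when adjusted over the list alone, and 21 were higher in both treated tumours. The median was 3.29 within pool 1 and 3.52 within pool 2. Type I interferon genes (34 measured) rose with a median of 0.49 (adjusted p = 0.038; p = 0.206 with an estimated correlation); 1 member, Ifit2, passed, 1 when adjusted over the list alone, and 22 were higher and 5 lower in both treated tumours. With plain library size the median was -0.08 and the adjusted p 0.142, and the adjusted p was 0.0509 without cells carrying markers of a second type, 0.104, 0.121 and 0.108 with pool 1, 3 or 4 left out, and 0.0531 without the tenth of cells with the fewest UMIs. Interferon gamma genes had a median of -0.13 (adjusted p = 0.0619) and 0 members passed.

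Further lists moved in neutrophils without a member that passed. Dendritic maturation genes rose (10 measured, median 1.19, adjusted p = 0.0243; p = 0.258 with an estimated correlation; 2 genes adjusted over the list alone), with Samsn1 at 2.03 ± 0.77 and Marcksl1 at 1.18 ± 0.72, both genes that neutrophils also express; the call ended with pool 1, 3 or 4 left out (adjusted p = 0.0722, 0.0517 and 0.249). Chemokine genes for T and NK cells rose (4 measured, median 1.33, adjusted p = 0.038; p = 0.231 with an estimated correlation; 1 gene adjusted over the list alone), with Ccl3 at 1.46 ± 0.76 and Ccl4 at 1.19 ± 0.74. That call ended with plain library size (adjusted p = 0.0739), without cells carrying markers of a second type (0.0681) and with pool 1, 3 or 4 left out (0.163, 0.108 and 0.239). Mitochondrial transcripts, a sign of RNA quality, fell (11 measured, median -0.84, adjusted p = 0.000179; p = 0.407 with an estimated correlation; 1 gene adjusted over the list alone). Their summed level was 6529 CPM untreated, 2958 in anti-CD40 tumour 1 and 6076 in anti-CD40 tumour 2. Without the tenth of cells with the fewest UMIs, 3 of the lists called in neutrophils lost their call, type I interferon genes among them.

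In monocytes, macrophages and dendritic cells, Mgl2, Ccl24, Ccl17 and Ciita were among the genes that fell, and Nr1h3, Lpl and Cd38 among those that rose. Mgl2 (chromosome 11, 70130329 to 70137550), for a lectin of macrophages and dendritic cells, fell by 5.31 ± 0.49 on the log2 scale (adjusted p = 5.27e-05), from 145 to 3.13 and 3.71 CPM. The chemokine genes Ccl24 and Ccl17 fell by 4.93 ± 0.70 (adjusted p = 0.00539) and by 3.41 ± 0.55 (adjusted p = 0.00973). Ciita (chromosome 16, 10480059 to 10528418), the master regulator of MHC class II genes, fell by 2.42 ± 0.38 (adjusted p = 0.00772), from 200 to 39.2 and 35.6 CPM. Nr1h3 (chromosome 2, 91184061 to 91202834), for the sterol sensor LXR alpha, rose by 4.26 ± 0.56 (adjusted p = 0.002), Lpl, for lipoprotein lipase, by 4.19 ± 0.63 (adjusted p = 0.0193), and Cd38, for an ectoenzyme that consumes NAD, by 3.90 ± 0.56 (adjusted p = 0.00416).

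Gdf15 (chromosome 8, 70629393 to 70632456), a cytokine gene induced by stress, had 0 UMIs in untreated myeloid cells and 50.2 and 94.2 CPM in the treated tumours, at least 13.8-fold higher (adjusted p = 0.00973). The formyl peptide receptor genes Fpr2 and Fpr1 rose, Fpr2 by 3.77 ± 0.49 (adjusted p = 0.002) and Fpr1 with a ratio of 12.3 (4.13 to 60.6), and Adgre4 rose with a ratio of 11.5 (3.83 to 56.4). The antioxidant genes Gsr and Slc7a11 rose by 2.85 ± 0.49 (adjusted p = 0.0163) and 2.66 ± 0.51 (adjusted p = 0.0263). Ptgs1, Gatm, Ch25h, Cdh1, B3gnt7, Ccdc152 and Flt1 fell, with log2 changes from -3.81 to -2.64. Exons of Fpr2 overlap Fpr3, those of Nr1h3 overlap Gm13783 and those of Ccdc152 overlap Selenop on the other strand, so that these counts are uncertain. Exons of Ciita overlap Dexi on the other strand, and those of Ptgs1, Ch25h and B3gnt7 also overlap a gene there, which makes their counts uncertain too. Cd40, the gene of the targeted receptor (chromosome 2, 165055627 to 165072948), stood at 66.2, 87.8 and 89.8 CPM (0.42 ± 0.41, adjusted p = 0.815).

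Some genes that rose are also markers of another cell type or of a single cluster of this class. S100a9, abundant in neutrophils, rose by 3.37 ± 0.55 (adjusted p = 0.0223), but without cells carrying markers of a second type its log2 change was -0.72 (adjusted p = 0.749). S100a9 is itself among the markers by which those cells were chosen, so that this fall follows in part by construction and does not show that neutrophils were the source. In this class of anti-CD40 tumour 1, S100a8 and S100a9 had 671 and 550 UMIs and Retnlg had 4. In neutrophils of that tumour they had 23023, 31578 and 6979, which argues against neutrophil RNA as the whole source there. In anti-CD40 tumour 2 the counts were 352, 593 and 76 in this class and 3294, 4975 and 890 in neutrophils. S100a8 is among the leading genes of the monocyte-like cluster. Cells carrying markers of a second type made up 1.94% of this class in the untreated tumour. They made up 19.2% in anti-CD40 tumour 1 and 133 of 1330 cells in anti-CD40 tumour 2. Such a count does not part captured pairs from cells with their own S100a8 and S100a9. Fscn1 in monocytes, macrophages and dendritic cells, a gene of mature dendritic cells, rose by 2.52 ± 0.45 (adjusted p = 0.0223), but its change was -2.58 (adjusted p = 0.441) without the mature dendritic cell-like, T cell-like and neutrophil-like clusters. Fscn1 leads the first of these, so that leaving it out removes cells chosen for this gene by construction.

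In this class 29 of 7099 genes passed, 12 higher and 17 lower, and 652 had an unadjusted p below 0.05. DESeq2 called 14, of which 11 were higher and 3 lower. All 29 kept their direction within pool 1, within pool 2 and in each treated tumour. The count was 21, 1, 14 and 10 with pool 1, 2, 3 or 4 left out, 8 without the tenth of cells with the fewest UMIs, and 226 without the monocyte-like cluster, 108 of whose 113 cells came from anti-CD40 tumour 1. The largest clusters differed between the tumours in part. Among the 1136 untreated cells, cluster 2 (led by Gatm, Cdh1 and Ccl24, 310 cells) and cluster 5 (Fcrls, Ms4a7 and Ccl7, 221 cells) were largest. In anti-CD40 tumour 1 they were cluster 7 (Chil3, Lcn2 and Saa3) and cluster 13 (Gdf15, Nr1h3 and Lpl), and in anti-CD40 tumour 2 cluster 6 (Pf4, Thbs1 and Ier3) and cluster 13. Cluster 2, whose leading genes also include Ciita, Mgl2 and Flt1, held 310 untreated cells and 8 and 34 treated cells. Cluster 13, whose leading genes also include Cd38, held 24 untreated cells and 102 and 261 treated cells. For these genes, a changed mix of clusters and a change within cells were not told apart.

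**Figure D3:**
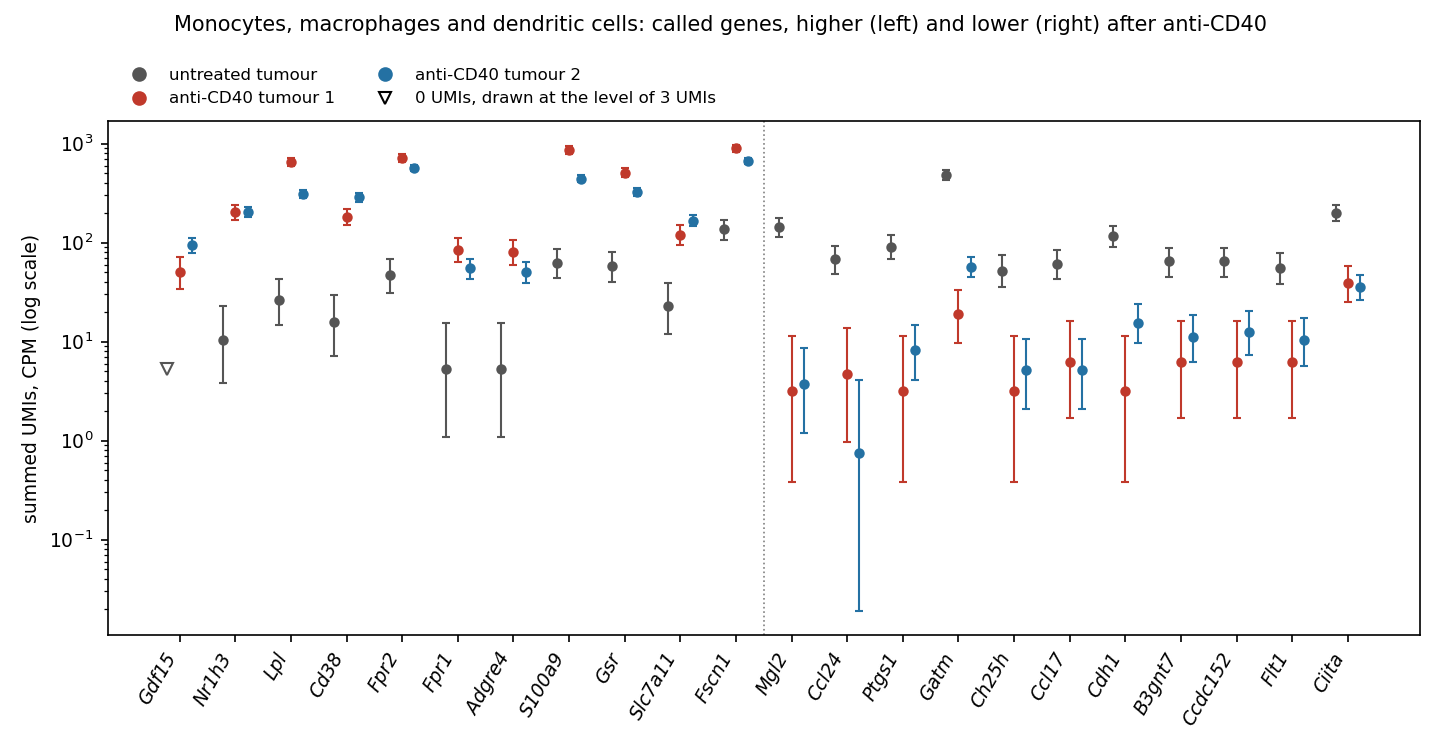
Level in monocytes, macrophages and dendritic cells (summed UMIs as CPM, log scale) of named genes that passed, higher left and lower right of the dotted line, in the untreated tumour (grey), anti-CD40 tumour 1 (red) and anti-CD40 tumour 2 (blue). Error bars are 95% Poisson counting intervals, and the open triangle marks 0 UMIs, drawn at the level of 3 UMIs. Mgl2 stands at 145, 3.13 and 3.71 CPM and Nr1h3 at 10.4, 202 and 205 CPM.

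Among the lists in these myeloid cells, MHC class II genes (10 measured) fell with a median of -1.25 (adjusted p = 6.52e-09; p = 0.181 with an estimated correlation). Ciita alone passed over all genes, 4 passed when adjusted over the list alone, and 8 were lower in both treated tumours. The median was -1.92 in anti-CD40 tumour 1 (-1.73 within pool 1 and -2.02 within pool 2) and -0.76 in anti-CD40 tumour 2. Interferon gamma genes (28 measured) fell with a median of -0.80 (adjusted p = 1.73e-07; p = 0.342 with an estimated correlation); Ciita alone passed, 3 passed when adjusted over the list alone, and 23 were lower and 3 higher in both treated tumours. The median was -1.08 in anti-CD40 tumour 1 (-1.09 within pool 1 and -0.92 within pool 2) and -0.58 in anti-CD40 tumour 2. Cluster 11, whose leading genes include Cxcl10 and Gbp2, held 154 untreated cells and 8 and 26 treated cells. Clusters 2 and 14, whose leading genes include Ciita, held 310 and 49 untreated cells, 8 and 4 of tumour 1, and 34 and 2 of tumour 2. Neither list was tested without these clusters, so that a loss of such cells and a fall within cells were not told apart. Type I interferon genes had a median of -0.19 (adjusted p = 0.132), with Isg15 at -0.44 ± 0.39.

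NF-kB genes (26 measured) rose with a median of 0.92 (adjusted p = 1.68e-05; p = 0.304 with an estimated correlation); 0 members passed, 4 when adjusted over the list alone, and Cxcl2 was at 2.50 ± 0.66 (adjusted p = 0.25). The median was 0.24 in anti-CD40 tumour 1 and 1.01 in anti-CD40 tumour 2, and within pools 1 and 2 the median was 0.08 and 0.26. Genes of SiglecF-high tumour neutrophils (32 measured) rose with a median of 0.42 (adjusted p = 0.0313; p = 0.62 with an estimated correlation), which was 0.06 within pool 1 and 0.05 within pool 2, and dissociation stress genes (22 measured) with a median of 0.49 (adjusted p = 0.0119; p = 0.425 with an estimated correlation), which was 0.25 and 0.14. In both lists 0 members passed, also when adjusted over the list alone, and the SiglecF-high call ended with pool 2 or 4 left out (adjusted p = 0.061 and 0.0673).

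Dendritic maturation genes (25 measured) rose in the same class with a median of 0.62 (adjusted p = 0.00314; p = 0.166 with an estimated correlation); Fscn1 rose, Ccl17 fell and 6 passed when adjusted over the list alone. Without the mature dendritic cell-like, T cell-like and neutrophil-like clusters the median was -0.11 and the list fell (adjusted p = 0.0239). Mature circulating neutrophil genes (16 measured) rose with a median of 1.38 (adjusted p = 0.000229; p = 0.141 with an estimated correlation); S100a9 passed, and 5 passed when adjusted over the list alone. The call ended without cells carrying markers of a second type, which were chosen in part by members of this list (median 0.56, adjusted p = 0.78), and without the monocyte-like cluster (median 0.98, adjusted p = 0.437). Of the 9 lists called in this class, 2 lost their call without the monocyte-like cluster. Regulatory T cell genes (7 measured) fell with a median of -0.69 (adjusted p = 0.0136; p = 0.467 with an estimated correlation; 1 gene adjusted over the list alone), but the median was 0.17 among members with at least 100 UMIs, and the call ended with pool 1 left out (adjusted p = 0.495). Its median was -1.44 in anti-CD40 tumour 1 and 0.04 in anti-CD40 tumour 2, 3 of 7 members were lower in both, and the T cell-like cluster of this class held 67, 0 and 29 cells. Mitochondrial transcripts (13 measured) fell with a median of -0.40 (adjusted p = 0.0128; p = 0.201 with an estimated correlation; 0 genes adjusted over the list alone) and were lower in both treated tumours for all 13; with pool 1 left out the adjusted p was 0.06.

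The mature dendritic cell-like cluster (44, 57 and 73 cells) held higher Cd40 after anti-CD40, with 2 UMIs in the untreated tumour and 36 and 51 in the treated tumours, a ratio of 6.71 (1.80 to 56.3; adjusted p = 0.0316). Marcksl1 rose by 1.81 ± 0.47 (adjusted p = 0.00969), Nfkbia, an inhibitor of NF-kB that NF-kB induces, by 1.15 ± 0.33 (adjusted p = 0.0276), and Ndrg1 by 2.09 ± 0.60 (adjusted p = 0.0299). The MHC class I genes H2-D1 and H2-Q7 rose by 1.22 ± 0.38 (adjusted p = 0.0423) and 1.41 ± 0.41 (adjusted p = 0.0314), with uncertain counts because such genes are near-identical. The MHC class II genes H2-Eb1, Cd74 and H2-Aa fell by 1.47 ± 0.29 (adjusted p = 0.000129), by 1.34 ± 0.30 (adjusted p = 0.00251) and by 0.98 ± 0.29 (adjusted p = 0.0319), and Ccl17 fell by 3.79 ± 0.58 (adjusted p = 1.23e-07).

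Genes with 0 untreated UMIs in this cluster included Psme2, a proteasome activator gene (at least 3.26-fold higher), Klf2 (at least 3.24-fold), Cd81 (at least 2.66-fold), Plat (at least 2.14-fold), Jund (at least 1.97-fold) and Ptgs2 (at least 1.76-fold). Nr4a3, H2az1 and Atox1 fell by 1.76 ± 0.50, by 1.55 ± 0.43 and by 1.51 ± 0.40, and the ribosomal genes Rpl35a, Rps21 and Rplp1 fell with log2 changes from -1.28 to -1.13. Of 1162 genes 41 passed, 30 higher and 11 lower, and 185 had an unadjusted p below 0.05. Among the genes that passed, those that led the cluster are not given as results. In pool 2 alone 39 of the 41 kept their direction, Ccl17 (2.58) and Rpl35a (0.54) being reversed, and 14, 21, 17 and 40 genes passed with pool 1, 2, 3 or 4 left out. DESeq2 called 2 genes, and 0 passed in cells thinned to 300 UMIs, which left 384 genes to test.

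In T cells, Klf2, Cxcr4, Il7r, Il10 and Ctla4 were among the genes that rose, and C1qc, Apoe and C1qa among those that fell. Klf2 (chromosome 8, 72319033 to 72321656), a transcription factor gene of quiescent and recirculating T cells, rose by 2.37 ± 0.44 (adjusted p = 1.19e-05), from 158 to 768 and 855 CPM. Cxcr4, a chemokine receptor gene, rose by 2.18 ± 0.47 (adjusted p = 0.000392), Il7r, a survival receptor gene, by 1.96 ± 0.48 (adjusted p = 0.0036), and Il10, an inhibitory cytokine gene, by 1.87 ± 0.47 (adjusted p = 0.00467). Ctla4 (chromosome 1, 60887000 to 60915832), an inhibitory receptor gene, rose by 1.29 ± 0.28 (adjusted p = 0.000354), from 893 to 2327 and 2090.3 CPM. Klf6, Fam107b, Bhlhe40 and Jund rose by 1.94 ± 0.42, 1.77 ± 0.44, 1.66 ± 0.46 and 1.41 ± 0.30, and Tsc22d3, a gene induced by glucocorticoids, with a ratio of 10.2 (3.32 to 50.8). Gzmb, for a cytotoxic protease, was at 0.01 ± 0.22 (adjusted p = 0.995), and Ccl5 at 1.13 ± 0.35 (adjusted p = 0.0541).

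The macrophage genes C1qc, Apoe and C1qa fell in T cells. C1qc went from 35 UMIs to 0, at least 22.9-fold lower, and the counts were lower by a ratio of 63.8 (16.97 to 538) for Apoe and 32.1 (10.3 to 161) for C1qa. H2-Eb1 fell by 4.19 ± 0.42 (adjusted p = 7.15e-20), H2-Aa fell by 3.53 ± 0.41 (adjusted p = 9.93e-15), Cd74 fell by 2.37 ± 0.34 (adjusted p = 8.32e-10) and Lyz2 fell by 2.51 ± 0.50 (adjusted p = 5.68e-05). H2-Ab1 and Tgm2 were lower by ratios of 25.5 (6.39 to 222) and 43.2 (6.98 to 1783), C1qb fell by 3.16 ± 0.59, Ccl4 fell by 2.36 ± 0.41 and Arg1 fell by 1.99 ± 0.56. The neutrophil genes S100a9 (at least 11.4-fold), S100a8 (ratio 26.0, 4.46 to 1046) and Retnlg (ratio 18.8, 3.18 to 764) were higher. Cells carrying markers of a second type made up 14.7%, 8.33% and 5.93% of the T cells. In T cells of 1865 genes 38 passed, 18 higher and 20 lower, and 209 had an unadjusted p below 0.05. DESeq2 called 3, of which 0 were higher and 3 lower, so that it called none of the genes that rose. Without the cells carrying markers of a second type 25 passed, 17 higher and 8 lower, 19 of them shared. C1qc, Apoe, C1qa, S100a9 and Retnlg are among the markers by which those cells were chosen. With pool 1, 2, 3 or 4 left out 26, 19, 32 and 27 passed, and 37 of 38 kept their direction in pool 2 alone, Tgfbi (0.42) being reversed.

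Of the lists in T cells, MHC class II genes fell (5 measured, median -3.53, adjusted p = 6.31e-24; p = 0.0786 with an estimated correlation), with 4 members passing and 5 when adjusted over the list alone; the median was -4.44 within pool 1 and -1.97 within pool 2, and -2.02 (adjusted p = 2.49e-06) without cells carrying markers of a second type. Suppressive myeloid genes fell (10 measured, median -2.74, adjusted p = 5.02e-17; p = 0.0689 with an estimated correlation), 6 members falling and Il10 rising, with 9 passing when adjusted over the list alone. Without the cells carrying markers of a second type 3 members were left, with a median of 0.17 (adjusted p = 0.961). Those cells were chosen in part by members of this list and of the mature circulating neutrophil list. A call lost without them therefore follows in part by construction. Mature circulating neutrophil genes rose (7 measured, median 0.74, adjusted p = 0.00265; p = 0.197 with an estimated correlation; 4 genes adjusted over the list alone), but the median was -0.36 within pool 1, and the call ended without those cells (adjusted p = 0.866) and with pool 2 or 3 left out (0.848 and 0.835). Dissociation stress genes rose (19 measured, median 0.79, adjusted p = 0.000841; p = 0.35 with an estimated correlation), with Jund passing and 5 when adjusted over the list alone, and a median of 0.10 within pool 1 and 0.67 within pool 2; with pool 4 left out the adjusted p was 0.122. Genes of SiglecF-high neutrophils fell (12 measured, median -0.58, adjusted p = 0.0168; p = 0.211 with an estimated correlation; 3 genes adjusted over the list alone), Ccl4 falling and Bhlhe40 rising, and the call ended without the cells carrying markers of a second type (adjusted p = 0.0808) and with pool 1 or 2 left out (0.22 and 0.0642). Cytotoxic effector genes (median 0.06, adjusted p = 0.293), exhaustion genes (0.03, adjusted p = 0.437) and regulatory T cell genes (0.13, adjusted p = 0.154) did not pass.

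In NK cells, granzyme genes of the Gzmc cluster fell. Gzmd (chromosome 14, 56129556 to 56132608) fell by 4.78 ± 0.59 (adjusted p = 2.1e-12), Gzmf by 4.40 ± 0.53 (adjusted p = 4.88e-12) and Gzmc by 1.94 ± 0.52 (adjusted p = 0.023), from 2067, 4219.8 and 3703 CPM in the untreated tumour; their sequences are near-identical, so that counts may be split between them. Klf2 had 0 untreated UMIs and was at least 4.41-fold higher (adjusted p = 0.00154), as was the activation marker gene Cd69 (at least 2.60-fold), with Snu13 (at least 2.80-fold) and Rbbp4 (at least 2.44-fold). The ratio was 19.2 (3.38 to 762) for Bhlhe40, 11.9 (2.08 to 476) for Cytip and 9.43 (2.56 to 78.7) for Cxcr4, and H3f3b rose by 2.20 ± 0.66. Ifitm2, whose counts are uncertain, Lgals3, Ptms and S100a11 fell by 3.62 ± 0.75, by 2.36 ± 0.55, by 1.88 ± 0.56 and by 1.84 ± 0.52.

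In NK cells of 794 genes 15 passed, 8 higher and 7 lower, and 87 had an unadjusted p below 0.05. DESeq2 called 1, which was lower, and 0 that were higher. All 15 kept their direction within pool 1 and within pool 2, and 2, 1, 16 and 6 passed with pool 1, 2, 3 or 4 left out. Without cells carrying markers of a second type, which made up 12.2%, 0% and 2.34%, 4 genes passed. MHC class II genes fell as a list (4 measured, median -4.01, adjusted p = 2.88e-07; p = 0.109 with an estimated correlation; 2 genes adjusted over the list alone), without a member that passed over all genes, and H2-Eb1 had 17, 0 and 2 UMIs. The macrophage genes C1qa and Apoe had 14, 0 and 3 and 9, 0 and 6 UMIs in the same cells, and putting aside 4 of 41 untreated NK cells with macrophage markers took the class II and Lyz2 level from 2102 to 651 CPM. Suppressive myeloid genes fell (6 measured, median -1.93, adjusted p = 0.000163, and p = 0.141 with an estimated correlation). Lgals3 alone passed, and 2 genes when adjusted over the list alone. The call ended without cells carrying markers of a second type (adjusted p = 0.104), which were chosen in part by members of this list. NF-kB genes rose (6 measured, median 1.56, or 1.26 with genes at 0 UMIs at their bound; adjusted p = 0.0203; p = 0.315 with an estimated correlation), with 0 members passing, also over the list alone; Nfkbia was at 1.45 ± 0.62. Cytotoxic effector genes had a median of 0.04 (adjusted p = 0.643), with Gzmc and Gzmf falling. The NK lists passed in 0 to 3 cases with a pool left out, and in 0 with pool 1 left out.

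Several lists passed in no cell type. The lowest adjusted p was 0.356 for MHC class I genes (myeloid cells other than neutrophils, median 0.10), 0.177 for glycolysis and hypoxia genes (the same cells, 0.45), 0.206 for myeloid chemokine genes (neutrophils, 0.91), 0.067 for ribosomal protein genes (T cells, 0.11) and 0.14 for proliferation genes (NK cells, 1.02). Tumour epithelial, fibroblast and endothelial, and red cell and platelet genes had fewer than 3 measured members in each cell type.

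The design also asked whether the interferon response after anti-CD40 differed between neutrophils and the other myeloid cells. In the joint fit 6 of 7700 genes differed, all with a higher change in neutrophils, and 430 had an unadjusted p below 0.05. They were the interferon-induced genes Ifit1 (difference of log2 changes 3.72 ± 0.87, adjusted p = 0.0331), Ifit3 (4.11 ± 0.94, adjusted p = 0.0243) and Ifit2 (0 untreated UMIs in neutrophils, adjusted p = 0.00512), and Ifitm6 (5.96 ± 1.02, adjusted p = 4.31e-05), Cd177 (6.35 ± 1.45, adjusted p = 0.0243) and Mgst1 (5.26 ± 1.27, adjusted p = 0.0476). Fitted differences of Ifitm6, Cd177 and Mgst1 rest on 3 or fewer untreated UMIs. In neutrophils Ifit1 stood at 244, 1615 and 1260.6 CPM in the scaling of the joint fit (untreated tumour, anti-CD40 tumours 1 and 2). These levels rest on 10, 756 and 159 of 23468, 712755 and 172591 UMIs, and depend on that scaling. In the other myeloid cells Ifit1 stood at 120, 32.6 and 78.2 CPM. With plain library size the difference of log2 changes was 2.41 for Ifit1 and 2.80 for Ifit3. In the other myeloid cells, cluster 11, whose leading genes include Ifit1, Ifit3 and Ifitm6, held 154 untreated cells and 8 and 26 treated cells; the difference was not tested without it.

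The median difference over all genes in this fit was 1.83, and 0.73 with plain library size, so that single genes and lists are to be read against it. Type I interferon genes (41 measured) had a median difference of 1.52 (adjusted p = 3.9e-07; p = 0.369 with an estimated correlation). This lay below the median of all genes and above the median of 0.83 among genes with at least 10 untreated UMIs in neutrophils. With plain library size the median was 0.21 (adjusted p = 0.0356), and that of the genes with at least 10 such UMIs -0.48. Within pool 1 it was 1.26 and within pool 2 1.96. Interferon gamma genes (28 measured) had a median difference of 1.46 (adjusted p = 0.0992), which was 0.46 with plain library size (adjusted p = 0.905). With plain library size 6 genes differed, 2 higher and 4 lower, and Ifitm6 and Ifit2 alone were shared.

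**Figure D4:**
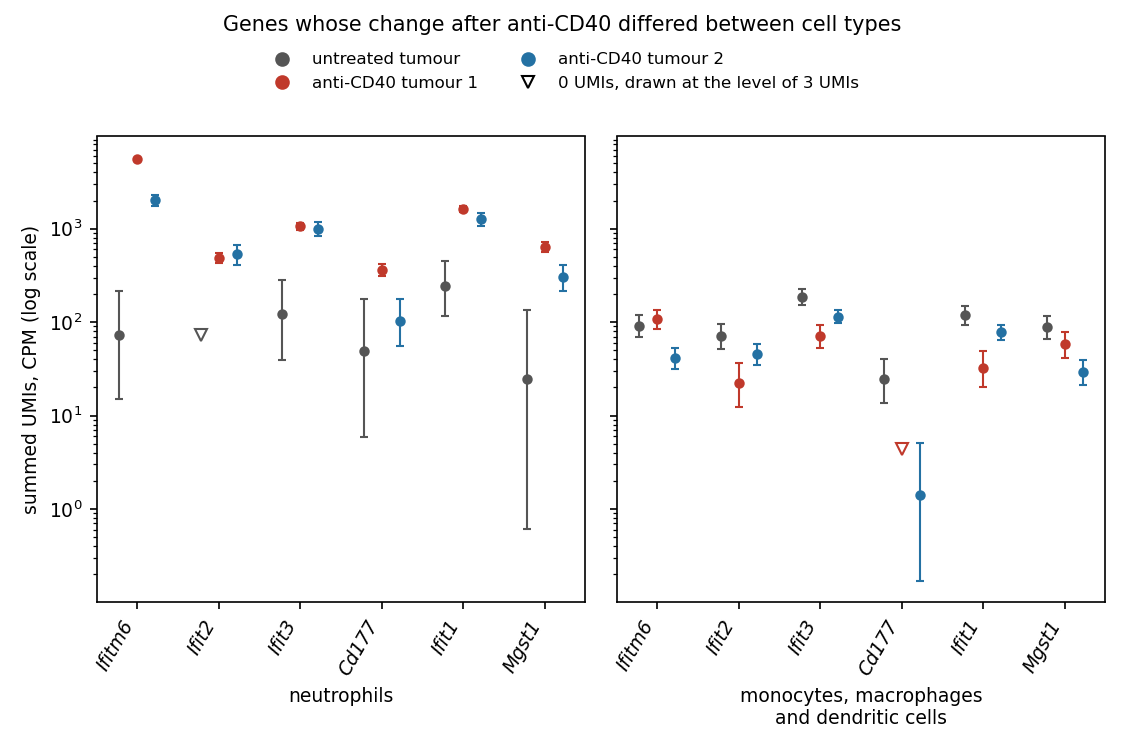
Level (summed UMIs as CPM in the scaling of the joint fit, log scale) of the 6 genes whose change differed, in neutrophils (left) and in monocytes, macrophages and dendritic cells (right), for the untreated tumour (grey), anti-CD40 tumour 1 (red) and anti-CD40 tumour 2 (blue). Error bars are 95% Poisson counting intervals, and open triangles mark 0 UMIs, drawn at the level of 3 UMIs. Ifit3 stands at 122, 1057 and 999 CPM in neutrophils and at 187, 71.1 and 114 CPM in the other myeloid cells.

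The treated tumours differed most from each other in neutrophils. Among genes with at least 100 UMIs, 178 of 1209 (14.7%) lay at least 2-fold apart between anti-CD40 tumours 1 and 2 in neutrophils, 199 of 3165 (6.29%) in the other myeloid cells, 9 of 231 (3.90%) in NK cells, 3 of 227 (1.32%) in T cells and 2 of 197 (1.02%) in mature dendritic cell-like cells. The minimum of 100 UMIs stands for another level in each cell type, so that unlike sets of genes are set side by side. The median absolute log2 difference was 0.475 in neutrophils, 0.372 in NK cells and 0.343 in the other myeloid cells. It was 0.248 in mature dendritic cell-like cells and 0.193 in T cells. Tumour and pool cannot be told apart here, since anti-CD40 tumour 1 lay in pools 1 and 2 and anti-CD40 tumour 2 in pools 3 and 4.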

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

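Neutrophils and the other myeloid cells differed in their response to anti-CD40 for 6 genes, by a test of the difference itself in a joint fit. Adjusted p was 4.31e-05 for Ifitm6, 0.00512 for Ifit2, 0.0243 for Ifit3 and for Cd177, 0.0331 for Ifit1 and 0.0476 for Mgst1, each with the higher change in neutrophils. For the list of type I interferon genes the adjusted p was 3.9e-07 (p = 0.369 with an estimated correlation). Its median difference of 1.52 lay below the 1.83 of all genes and above the 0.83 of genes with at least 10 untreated UMIs in neutrophils. With plain library size its median was 0.21 (adjusted p = 0.0356), against 0.73 and -0.48, so that its place depends on the genes it is set against. With plain library size the 6 genes kept their direction, and Ifitm6 (adjusted p = 0.00131) and Ifit2 (adjusted p = 0.0334) alone passed. No test of a cause was run for these differences, and the treatment stays open as an untested explanation.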

How the results depend on the processing

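The alternatives that left out cells with markers of a second type, subsets or clusters were chosen after the data were seen, and the others beforehand. No paired analysis was possible because there was 1 untreated tumour. Where a value below differs from the report's, the cause was not tested, except where fewer cells or genes entered by construction.

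Genes called were 12 in neutrophils, 29 in monocytes, macrophages and dendritic cells, 41 in mature dendritic cell-like cells, 38 in T cells and 15 in NK cells. The DESeq2 Wald test called 14 in monocytes, macrophages and dendritic cells, 2 in mature dendritic cell-like cells, 3 in T cells and 1 in NK cells. Those in T and NK cells were all lower. DESeq2 size factors gave 7 in neutrophils, and plain library size 89 in monocytes, macrophages and dendritic cells. With no low-count filter there were 7 in neutrophils, 141 in monocytes, macrophages and dendritic cells, 17 in mature dendritic cell-like cells and 8 in NK cells. In cells thinned to 300 UMIs there were 5, 65, 0, 9 and 1 in the order above. Without cells with markers of a second type there were 53 in monocytes, macrophages and dendritic cells, 25 in T cells and 4 in NK cells. Without N1a and N1b there were 2 in neutrophils, and without the 10% of cells with the fewest UMIs 8 in monocytes, macrophages and dendritic cells. In that class there were 56 without the mature DC-like, T cell-like and neutrophil-like clusters and 226 without the monocyte-like cluster. With a pool left out the ranges were 3 to 23, 1 to 21, 14 to 40, 19 to 32 and 1 to 16 in the order above.

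Single genes reversed in some settings. In monocytes, macrophages and dendritic cells S100a9 was at -0.72 (3.37 in the report) without cells with markers of a second type, and Fscn1 in monocytes, macrophages and dendritic cells at -2.58 (2.52) without the mature DC-like, T cell-like and neutrophil-like clusters. In pool 2 alone, Ccl17 in mature dendritic cell-like cells was at 2.58 (-3.79), Rpl35a in mature dendritic cell-like cells at 0.54 (-1.28) and Tgfbi in T cells at 0.42 (-2.36). With a pool left out Rpl35a ranged from -1.67 to 0.49.

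Lists called in neutrophils (5 in the report) were 8 without N1a and N1b, 2 without the 10% of cells with the fewest UMIs and 3 to 9 with a pool left out. In T cells (5) they were 2 without cells with markers of a second type and 3 to 4 with a pool left out, and in NK cells (3) 0 to 3. The dendritic_maturation list in monocytes, macrophages and dendritic cells was at -0.11 (0.62) without the mature DC-like, T cell-like and neutrophil-like clusters. The regulatory_T list in monocytes, macrophages and dendritic cells was at 0.17 (-0.69) among genes with at least 100 UMIs. The mature_circulating_neutrophil list in T cells was at -0.36 (0.74) in pool 1 alone. The interferon_gamma_induced list in neutrophils against other myeloid cells was at 0.46 (1.46) with plain library size and 1.27 in pool 1 alone. Of the 22 lists called, 22 kept direction and call with DESeq2 size factors and 20 with plain library size, and 14 of 21 without cells with markers of a second type. Some lists hold markers by which those cells were chosen, so that their losses follow in part by construction. The counts of lists above all rest on the preset correlation of camera. With an estimated correlation, none of the 22 lists had a camera p below 0.05, even before adjustment.

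In cells with at least 500 UMIs, the share in anti-CD40 tumour 2 was 10.3% (11.8%) for neutrophils and 75.95% (73.3%) for monocytes, macrophages and dendritic cells. Without cells with markers of a second type, it was 61.6% (57.1%) and 32.01% (36.5%) in anti-CD40 tumour 1. The T cell share of the untreated tumour was 12.5% (10.7%) in pool 2 alone and 9.24% to 12.5% with a pool left out. Genes at least 2-fold apart between the treated tumours were 7.21% in pool 3 alone and 7.28% in pool 4 alone (6.29%) in monocytes, macrophages and dendritic cells, 7.52% and 1.62% (3.90%) in NK cells, 17.7% in pool 4 alone (14.7%) in neutrophils and 0% in pool 3 alone (1.32%) in T cells. Settings with 1 tumour per condition give values without a test, and the interaction was not rerun with pools left out.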

Other observations

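The genes Klf2, Cxcr4 and Bhlhe40 rose in both T and NK cells by the edgeR test. The DESeq2 Wald test called 0 higher genes in either cell type. Of 735 genes tested in both cell types, 11 rose in T cells and 8 in NK cells, with 3 in common. S100a11 fell in both. Both cell types came from the same tumours, so that genes in common can arise from the shared animals alone, and the overlap was not tested.

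The fluorescent reporter of interleukin-12 p40 was read in monocytes, macrophages and dendritic cells at 98.3 CPM (74.2 to 128) in the untreated tumour, 148 CPM (118 to 182) in anti-CD40 tumour 1 and 63.9 CPM (51.6 to 78.3) in anti-CD40 tumour 2, and at 0 UMIs in neutrophils, T cells and NK cells. Of its 56, 88 and 93 UMIs, 39, 87 and 93 lay in the mature dendritic cell-like cluster, which made up 3.87%, 12.7% and 5.49% of this class. Within that cluster the level was 2161 CPM (1537 to 2954) untreated, 1686 (1350 to 2080) in anti-CD40 tumour 1 and 1346 (1086 to 1649) in tumour 2. The higher class level of tumour 1 was thus not seen within the cluster. The reporter is among the leading genes of that cluster, so that its gathering there follows in part from how the cluster was defined. Il12b itself had 0 UMIs in the untreated tumour and 1 UMI in each treated tumour. In neutrophils thinned to 300 UMIs, the interferon gene Rsad2 was detected in 53.7%, 36.6% and 43.5% of cells, Isg15 in 46.3%, 48.4% and 51.0%, and Ifit1 in 12.2%, 21.3% and 19.5% (untreated tumour, anti-CD40 tumours 1 and 2).

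The tests of sequencing pools, of single animals, of the subset mix and of T cells without a macrophage UMI were chosen only after the result was seen. The neutrophil share was higher in both treated tumours. Thinning treated cells to the untreated depth left at least 10.2% neutrophils in either tumour, above the untreated upper bound of 4.60%. For anti-CD40 tumour 2 this argues against a loss of shallow neutrophils below the minimum of UMIs. For anti-CD40 tumour 1 the step could not decide, since too few cells were lost (1226 before and 1016 on average after). Cells kept the names given at full depth, so that an effect of depth on naming was not tested. Within pools 1 and 2 the intervals of anti-CD40 tumour 1 and the untreated tumour lay at least 47.0 percentage points apart, which argues against pools for that tumour. The treated tumours differed 4.82-fold from each other, and with 1 untreated animal the treatment and the spread between animals cannot be told apart.

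The list of mature circulating neutrophil genes was higher in treated neutrophils. At the untreated mix of subsets, 68.6% of its median log2 ratio was left in anti-CD40 tumour 1 and 81.4% in tumour 2, which argues against the mix of subsets as the whole cause for the list. Without N1a and N1b, which leaves fewer cells, all 12 single genes called kept their direction and 2 were still called. In 1000 draws of tumour 2 at the untreated numbers of cells and UMIs, the lowest median log2 ratio against tumour 1 was -1.89. The untreated value was -1.94, which argues, narrowly, against the sampling of few cells and UMIs as the whole cause. The cells drawn were deeper (median 668 against 435 UMIs), and their sums were thinned at random. A bias of shallow cells could therefore not be seen. An effect of the treatment stays open and was not tested apart from the animal.

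T cells of the untreated tumour held macrophage transcripts, 235 marker UMIs in 150 cells. Free RNA spread evenly would leave 20 to 55 cells without such a UMI in 1000 draws, and 117 had none, which argues against it; 21 cells held at least 3, against 22 to 44 in the draws. The bound set beforehand for that count was on the wrong side, since RNA gathered in few cells lowers it. Putting those 21 cells aside left 30.7% of the MHC class II and Lyz2 level, so that a few T cells captured with a macrophage may account for most of the untreated level. A difference between the tumours was left. After this step the level was 1454 CPM untreated and 259 and 313 CPM treated (4741, 762 and 439 CPM before). T cells with fewer than 3 marker UMIs stayed in, and untreated T cells were shallower (median 475.5 against 778 and 651 UMIs). Captured pairs missed by this cut were therefore not excluded as a source of what was left. An effect of the treatment on T cells stays open as untested.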
